A study of Homo sapiens with 10 samples.

How the data were processed

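Small RNA was sequenced from 8 microdissected benign human prostate epithelium samples and from 1 primary culture of prostate epithelial cells under 2 treatments, 10 libraries in all. Per the labels' protocols, epithelium was cut from frozen tissue by laser-capture microdissection, 500 ng of total RNA from each tissue sample and 1000 ng from each culture entered the TruSeq Small RNA kit, and the libraries were read for 51 cycles on a HiSeq 2500. The tissue libraries and the 2 cell libraries ran on separate lanes, per the labels, so lane, input and material differ together between cells and tissue. The protocol text of 2 of the 4 control tissue libraries words the lane differently from that of the other tissue libraries, and an alternative left those 2 out.

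The authors deposited 1 table of expected counts per library for each of 6 small RNA classes, 60 tables in all: miRNA, rRNA, snoRNA, snRNA, tRNA and piRNA. Not all of these deposited expected counts are whole numbers: 83.5% of the piRNA values are, 78.7% of the miRNA values and 9.9% of the tRNA values; the smallest value listed is 0.1, and a feature that a table does not list was taken as 0. The submitters' processing notes name cutadapt, without a version, and the genome build hg19. The aligner, the counting program and the rule that splits a read between features are not given in the sources used here. miRNA features are hairpins (hsa-mir-16-1 and hsa-mir-16-2 are separate features), so the arms of a hairpin are not told apart, and copies of 1 mature miRNA share reads. piRNA features carry piR names. The rRNA, snoRNA, snRNA and tRNA features are numbered and the files do not pair the numbers with names, so at most 2 of them are printed per direction and comparison, and subclasses of these RNAs were not analysed here. The reference annotation at hand (GENCODE release 29, assembly GRCh38) is of another build than hg19, so it was used for gene names and for which genes overlap, and no coordinates are given.

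Expected counts were rounded to whole numbers before the count models. Tissue groups were compared class by class with edgeR 4.0.16 in R 4.3.3: features were kept by filterByExpr with a minimum count of 10, libraries were scaled by TMM factors within the class, and the quasi-likelihood test was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Levels compared between the tissue groups are CPM of the features kept, with TMM-scaled library sizes. Levels in cells, and in control tissue where it is set against cells, are CPM of the class total without TMM factors. The SE of an edgeR log2 fold change is its absolute value over the square root of the quasi-likelihood F statistic. miRNA lists fixed before the data were examined were tested with camera at a preset correlation of 0.01 and with fry (limma 3.58.1), for lists with at least 3 tested hairpins. The 14 lists were the let-7 family, the miR-200 family with miR-205, the miR-183 cluster, the miR-17-92 cluster with its paralogs, the miR-34 family, the miR-15/16 family, the miR-99/100 and miR-125 family, the 14q32 cluster, vitamin D-linked miRNAs, prostate cancer-linked miRNAs, and markers of stroma and smooth muscle, of endothelium, of blood cells and of other organs. Class shares were compared by a two-sided exact permutation test over the 70 assignments of 8 libraries, whose smallest p is 0.0286, adjusted over the 6 classes.

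The 2 cell libraries have no replicates, so no p-value is given for them. Ratios are of class CPM with 0.5 added to each count, over features with a mean of at least 100 counts, with exact (Clopper-Pearson) 95% intervals on the 2 counts. PCR reads without molecular identifiers are not independent molecules, so these intervals cover counting error only. Vehicle cells were set against the range of the 4 control tissues in the same way, over hairpins with at least 100 counts in the cells or a mean of 100 in control tissue. A list's median was placed among 10000 random lists of the same size, drawn within 20 ranks of each member's mean level. The agreement of tissue and cell fold changes was measured by Spearman's rho across hairpins with at least 100 counts in both cell libraries, with a two-sided exact permutation test over the same 70 assignments.

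The features named were set by a rule written before the data were examined. In tissue these are the miRNAs past the threshold, with the 10 of smallest unadjusted p where fewer than 10 pass, and in each other class the 3 of smallest unadjusted p where none passes. For abundance they are the 10 most abundant miRNAs and the 3 most abundant features of each other class in control tissue. In cells they are the 10 miRNAs and the 3 features of each other class with the largest ratio in each direction, and for vehicle cells against control tissue the 10 largest differences in each direction outside the range of the 4 tissues. From each list 2 to 4 members of smallest unadjusted p are named, with copies of 1 miRNA counted as 1. The exceptions are the endothelial list, with 1 tested hairpin, and the other-organ list, with only copies of mir-9 tested. Another exception is the blood cell list, where the further hairpins were chosen after their values were seen.

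In data simulated from the tissue means with known folds, the edgeR test called 24.6% of miRNAs changed 2-fold, 86.9% of those changed 4-fold and all of those changed 8-fold, over 546 hairpins. For tRNA features the shares were 9.8% at 2-fold and 50% at 4-fold, over 364 features. Of these simulated features, 364 hairpins and 243 tRNA features were left unchanged. With so many true changes the adjusted threshold is easier to pass than where few features change. The shares can therefore overstate the power in the tissue data. In simulated cell counts over 571 hairpins, 94.4% of the intervals held the true ratio. No libraries of 1 group agreed within sampling noise: the lowest chi-square per degree of freedom between any pair was 142.7. Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, no filter on low counts, each library left out in turn, the replicate number as a block, a library size summed over the 6 classes, and other count minimums, denominators and correlation measures. Computations outside R used Python 3.11.15 with scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.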

Results

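The 6 deposited classes of small RNA were counted in benign prostate epithelium of 4 prostates under a control vitamin D3 supplement (400 IU a day) and of 4 prostates under a high supplement (40000 IU a day), each for 3 to 8 weeks. They were also counted in 1 primary culture of prostate epithelial cells treated for 24 h with ethanol vehicle or with 50 nM of 1,25D (calcitriol, the hormonally active form of vitamin D). The 8 tissue libraries held 7453388 to 10291248 counts over the 6 classes, of which 3079417 to 5125706 were miRNA. The vehicle and 1,25D cell libraries held 51892555 and 73011087 counts, of which 39305081 and 51412641 were miRNA. Each tissue library is from a separate prostate, and p-values measure the spread between these libraries.

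The first question was which small RNAs make up the epithelium. miRNA was the most abundant class in control tissue, at 44.6% ± 9.23 of the counts (SD, n = 4), followed by tRNA at 19.4% ± 13.1, piRNA at 17.4% ± 1.30, rRNA at 9.09% ± 1.45, snoRNA at 8.68% ± 2.59 and snRNA at 0.899% ± 0.162. The tRNA share varied most, from 10.6% to 38.7% between control libraries. The most abundant miRNA hairpin was mir-143, a miRNA known from smooth muscle, with 13.3% ± 5.17 of miRNA counts in control tissue. mir-10b followed with 5.73% ± 0.923, mir-375 with 4.89% ± 2.48 and mir-205, a miRNA of basal epithelium, with 4.68% ± 0.204. mir-148a held 4.15% ± 1.68, mir-22 held 3.30% ± 1.59, mir-92a-1 held 3.00% ± 1.10 and mir-21 held 2.86% ± 1.60. The 2 copies of mir-26a, which share reads, were listed at 2.83% ± 1.15 and 2.82% ± 1.15. These 10 hairpins together took 47.5% ± 5.85 of miRNA counts in control tissue and 47.8% ± 3.24 in high vitamin D tissue (n = 4 each).

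Among piRNA features, hsa_piR_016735 held 66.6% ± 5.88 of the piRNA counts in control tissue and 62.2% ± 13.02 in high vitamin D tissue, and 22.8% in vehicle cells. hsa_piR_015026 and hsa_piR_014620 followed in control tissue with 6.15% ± 0.241 and 5.46% ± 1.58. The other classes were also led by few features in control tissue: the 3 most abundant held 22.4%, 21.4% and 12.9% of rRNA counts, 19.6%, 8.70% and 5.77% of snoRNA counts, and 24.9%, 20.7% and 9.01% of snRNA counts. The tRNA counts were spread more evenly over features, with 3.65%, 3.65% and 3.53% on the 3 most abundant. These 3 features also had nearly equal shares in high vitamin D tissue (5.63%, 5.63% and 5.52%). Only 9.9% of tRNA values are whole numbers, so reads may be split between copies. An even spread over features is then not an even spread over separate tRNAs.

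Class composition was then compared between the supplement groups. piRNA took 20.8% ± 2.19 of the counts in high vitamin D tissue against 17.4% ± 1.30 in control tissue, and snRNA 1.09% ± 0.0847 against 0.899% ± 0.162 (n = 4 each). Neither share passed the threshold (exact permutation test, adjusted p = 0.171 for both). miRNA (42.2% ± 5.73 in high vitamin D tissue), tRNA (16.2% ± 6.55), rRNA (9.87% ± 0.834) and snoRNA (9.91% ± 1.61) did not pass either, with adjusted p of 0.771, 0.771, 0.629 and 0.686 in the same exact test. The smallest p this test can give is 0.0286, and a single class at that p would not pass after adjustment over the 6 classes. A failure to pass is therefore weak evidence that a share did not differ.

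**Figure D1:**
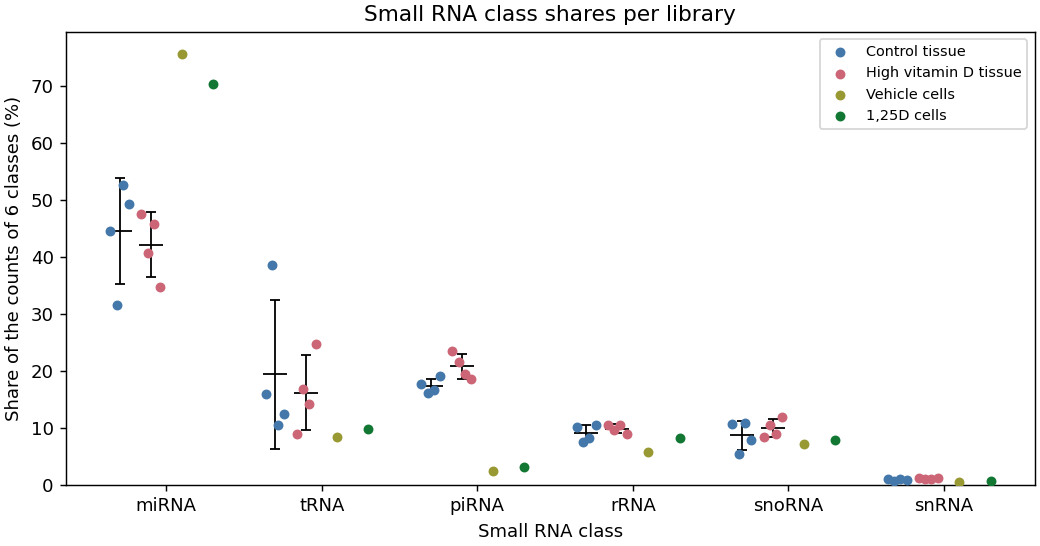
Share of the counts of 6 small RNA classes (y axis, percent) by class (x axis) in each library. Points are libraries and bars the mean and SD of the 4 control and 4 high vitamin D tissues; miRNA holds 75.7% of the counts in vehicle cells against 44.6% on average in control tissue, and piRNA 2.36% against 17.4%.

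The main comparison asked which miRNAs differ in epithelium between the high and the control supplement. The largest difference by p was that of mir-146a, a miRNA known as a brake on NF-kB signalling in immune and epithelial cells. It stood at 2168 CPM ± 2417 in control tissue and 178.5 CPM ± 39.2 in high vitamin D tissue (SD, n = 4 each), a log2 fold change of -3.60 ± 0.77 (SE). Without control replicate 4 the log2 fold change was -2.45. All 4 high vitamin D libraries (140.0 to 230.6 CPM) lay below all 4 control libraries (394.9 to 5626 CPM). The adjusted p of edgeR's quasi-likelihood test was 0.419, and that of DESeq2 was 0.00032 at a log2 fold change of -3.56. Over the 546 hairpins tested, edgeR called none past 0.05, with 5 higher and 10 lower at an unadjusted p under 0.05. DESeq2, run without the count filter over 1814 hairpins, called mir-146a alone, with 23 higher and 20 lower at an unadjusted p under 0.05. limma-voom, over the 546, called none, with 6 higher and 5 lower at an unadjusted p under 0.05.

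The other 9 hairpins of smallest p did not pass edgeR's or DESeq2's test. 5 of them were lower in high vitamin D tissue: mir-409, at a log2 fold change of -0.97 ± 0.29 (SE), mir-135b, at -1.80 ± 0.61, mir-138-2, at -2.14 ± 0.79, mir-146b, at -1.10 ± 0.41, and mir-223, a granulocyte and monocyte miRNA, at -1.62 ± 0.61. Without the 2 control libraries of different lane wording, mir-138-2 was at 0.21 (-1.31 without control replicate 1 alone), and without control replicate 4, mir-223 was at -0.61 and mir-146b at -0.68. 4 were higher: mir-6068, at 2.37 ± 0.75, mir-655, at 2.20 ± 0.63, mir-4485, at 1.98 ± 0.54, and mir-4461, at 1.55 ± 0.56. Without high vitamin D replicate 4, mir-6068 was at 1.64, mir-4485 at 1.30 and mir-4461 at 0.98. With 1 library left out in turn, mir-655 ran from 1.49 to 2.60. These 4 were scarce, with means of 2.24 to 17.6 CPM in control tissue. mir-146b, which shares its seed with mir-146a, stood at 1294 CPM ± 674 in control tissue and 605 CPM ± 196 in high vitamin D tissue (n = 4 each).

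**Figure D2:**
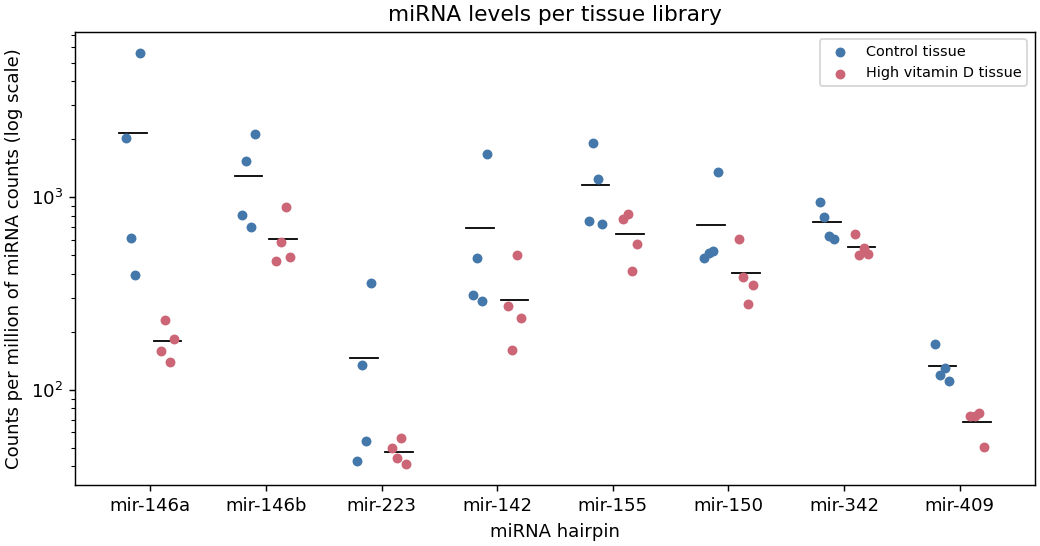
Level of 8 miRNA hairpins (y axis, CPM with TMM-scaled library sizes, log scale) in the 4 control and 4 high vitamin D tissue libraries, with points for libraries and black lines for group means. For mir-146a the control libraries span 394.9 to 5626 and the high vitamin D libraries 140.0 to 230.6, with no overlap.

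Camera at its preset correlation called 3 miRNA lists between the tissue groups, and none of these calls held with an estimated correlation. Of the 31 tested hairpins of the 14q32 cluster, an imprinted cluster in the DLK1-DIO3 region, 27 were lower in high vitamin D tissue, with a median log2 fold change of -0.36 and an adjusted p of 0.0201 in camera, against adjusted p = 0.899 with an estimated correlation. Its members of smallest p were mir-655 (2.20, the opposite direction), mir-409 (-0.97) and mir-758 (-0.76). The let-7 family, linked to differentiation, had 11 of 12 hairpins higher, with a median of 0.13 (camera adjusted p = 0.0274, and adjusted p = 0.899 with an estimated correlation). Its hairpins let-7a-1, let-7a-2 and let-7a-3, which share reads, were at 0.35, 0.35 and 0.34, and let-7f-2 was at 0.21. The tested other-organ markers were only the 3 copies of mir-9, a neural miRNA, at 0.87, 0.80 and 0.78 (camera adjusted p = 0.0091, and adjusted p = 0.607 with an estimated correlation). These copies share reads and are 1 measurement listed 3 times, so this p is not evidence from a list, and with copies summed the list had too few members to test. None of the members passed alone, over all hairpins or adjusted over the list alone (0 of 31, 0 of 12 and 0 of 3). fry, which asks whether a list moves on balance one way, gave p of 0.361 for the 14q32 cluster, 0.561 for let-7 and 0.143 for mir-9. Scaling by the total of all 6 classes moved the median of all hairpins by -0.22, and the let-7 median with it to -0.067.

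These list calls also depended on single libraries and on settings. With 1 library left out, the 14q32 median ran from -0.51 to -0.14 and the mir-9 median from 0.50 to 1.61. The 14q32 call ended without control replicate 2 (adjusted p = 0.438) or 3 (0.827) and without high vitamin D replicate 1 (0.128), 2 (0.143) or 4 (0.362), and the mir-9 call ended without control replicate 3 (0.172), without the 2 control libraries of different lane wording (0.080) and without a filter on low counts (0.177, with a median of 0.45 over 8 other-organ hairpins). The let-7 call ended without high vitamin D replicate 1 (0.201) or 2 (0.143), without the filter (0.141) and with copies summed (0.133), and its median was -0.047 without control replicate 1 (0.481) and -0.11 without the 2 control libraries of different lane wording (0.107), all in camera. let-7a-1 ran from 2252 to 32690 CPM between control libraries and from 18980 to 29460 CPM between high vitamin D libraries.

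In the blood cell list the 5 leukocyte hairpins were lower in high vitamin D tissue: mir-223 (-1.62 ± 0.61, SE), mir-142 (-1.24 ± 0.60), mir-155 (-0.85 ± 0.38), mir-150 (-0.82 ± 0.41) and mir-342 (-0.43 ± 0.26). The red cell hairpins mir-451a, mir-144 and mir-486-1 were at -0.12, 0.12 and 0.41, and the list as a whole did not pass (camera adjusted p = 0.0708, and adjusted p = 0.607 with an estimated correlation). Control replicate 4 had the highest mir-223 (356.8 CPM) and mir-142 (1683 CPM) of the 8 libraries; without it 5 of the 9 hairpins were lower, the list median was -0.24 and its mean -0.062, mir-223 was at -0.61 and the list's adjusted p was 0.343. In camera the list passed without control replicate 1 (0.0125), without high vitamin D replicate 4 (0.0299), without the 2 control libraries of different lane wording (0.0051), without a filter on low counts (0.0270) and with copies summed (0.0381), against the 0.607 over all 8 libraries with an estimated correlation. Of the vitamin D-linked miRNAs, 13 of 16 hairpins were lower, with a median of -0.29 (camera adjusted p = 0.113, and adjusted p = 0.811 with an estimated correlation), and mir-181a-1 was at -0.44, mir-22 at -0.44 and mir-331 at -0.42. In camera this list passed without control replicate 1 (0.0139), without high vitamin D replicate 3 (0.0446) and without the 2 control libraries of different lane wording (0.0307), at medians of -0.13, -0.35 and -0.13, against the 0.811 over all 8 libraries with an estimated correlation. The stromal and smooth-muscle markers had a median of -0.15 and a mean of -0.069 over 11 hairpins, while camera's direction was up (adjusted p = 0.927), with mir-133b at -0.56, mir-1-1 at 0.56 and mir-143 at -0.27. The single endothelial hairpin mir-126 was at 0.048. In these lists, too, 0 members passed over all hairpins or adjusted over the list alone.

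The remaining lists did not pass in camera. The miR-200 family with miR-205, characteristic of epithelium, had a median of 0.12 over 7 hairpins (adjusted p = 0.361), with mir-205 at 0.30 and mir-200c at 0.28. The miR-34 family, targets of p53, had a median of 0.45 over 3 hairpins (adjusted p = 0.361), with mir-34b at 0.60, mir-34c at 0.45 and mir-34a, in the opposite direction, at -0.38. The miR-17-92 cluster and its paralogs had a median of -0.047 over 15 hairpins while their mean was 0.066 (adjusted p = 0.361), with mir-92a-1 at 0.44 and mir-20a at 0.50. The miR-99/100 and miR-125 family had all 6 hairpins lower at a median of -0.17 (adjusted p = 0.728), with mir-125b-2 at -0.20, mir-125b-1 at -0.21 and mir-99b at -0.22. The prostate cancer-linked miRNAs had a median of 0.079 and a mean of -0.029 over 11 hairpins (adjusted p = 0.733), with mir-21 at -0.47 and mir-25 at 0.25. The miR-183 cluster had a median of -0.32 over 3 hairpins, while camera's direction was up (adjusted p = 0.987), with mir-183 at -0.50 and mir-96 at 0.35. The miR-15/16 family had a median of -0.12 over 8 hairpins (adjusted p = 0.940), with mir-503 at -1.17 and mir-497 at -0.19. Scaling by the total of all 6 classes, which moved the median of all hairpins by -0.22, moved the medians of the miR-200 family with miR-205 and of the prostate cancer-linked miRNAs with it to -0.068 and -0.19, and RLE factors, which moved all by 0.064, moved that of miR-17-92 to 0.021. In camera the miR-15/16 family passed without control replicate 1 (0.0102) and without the 2 control libraries of different lane wording (0.0307), where over all 8 libraries it had adjusted p = 0.991 with an estimated correlation. Without control replicate 4, miR-17-92, miR-200 with miR-205, miR-99/100 with miR-125 and the prostate cancer-linked miRNAs passed in camera, each at 0.0467. Over all 8 libraries these had adjusted p = 0.954, 0.924, 0.979 and 0.979 with an estimated correlation. In each of these lists 0 members passed, over all hairpins or adjusted over the list alone.

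**Figure D3:**
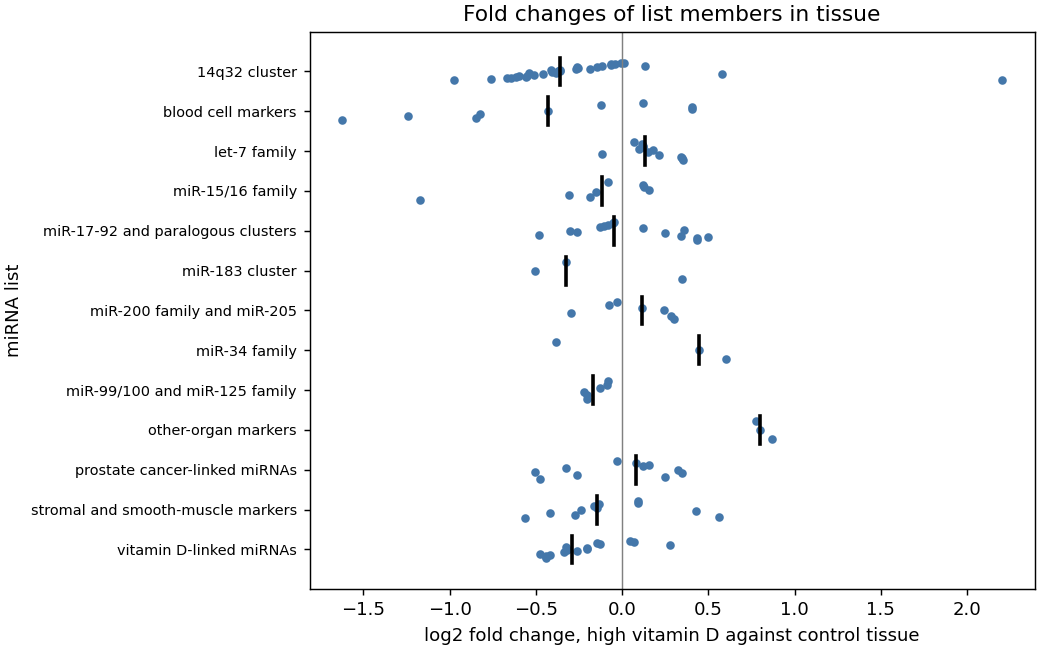
log2 fold change, high vitamin D against control tissue (x axis), of each tested member of 13 miRNA lists (y axis). Points are hairpins and black bars are list medians, which run from -0.43 for blood cell markers to 0.80 for the 3 copies of mir-9.

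In the other classes edgeR called 0 features between the tissue groups. At an unadjusted p under 0.05 there were 2 higher and 14 lower of 472 snoRNA features, 6 and 4 of 174 snRNA features, 17 and 5 of 364 tRNA features, 13 and 11 of 359 piRNA features, and 3 and 4 of 124 rRNA features. DESeq2, again without the count filter, and limma-voom called 0 in each of these classes as well. The piRNAs of smallest p were hsa_piR_014003 at a log2 fold change of 2.39 ± 0.59 (SE), hsa_piR_017490 at 2.13 ± 0.60 and hsa_piR_000663 at -1.29 ± 0.39. Their edgeR adjusted p was 0.320. Among numbered features, 1196_snRNA was at 0.98 ± 0.26, 70_tRNA at 2.00 ± 0.55, 552_snoRNA at -0.86 ± 0.21 and 135_rRNA at -0.84 ± 0.30. With no filter on low counts, edgeR called 17 piRNA features, 12 higher and 5 lower, and 1 snoRNA feature lower. Scaling by the total of all 6 classes moved the median of all features by 0.27 for snoRNA, 0.19 for snRNA and -0.75 for tRNA; at an unadjusted p under 0.05 there were then 18 higher and 2 lower snoRNA features and 2 higher and 83 lower tRNA features, and 4 higher and 32 lower miRNAs.

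The cell libraries asked how 24 h of 1,25D changes small RNAs in cultured prostate epithelial cells, with no replicate of either treatment. Of 571 miRNA hairpins with a mean of at least 100 counts, 0 differed 2-fold or more between the 1,25D and the vehicle library, and 95% of the log2 ratios lay between -0.39 and 0.58. The hairpins highest in the 1,25D library were mir-7641-2 at a log2 ratio of 0.85 (95% interval 0.80 to 0.90) and mir-4532 at 0.85 (0.81 to 0.88), followed by mir-6799, mir-1291, mir-383, mir-495, mir-3607, mir-4675, mir-139 and mir-4634, at 0.64 to 0.78. The lowest were mir-3129 at -0.81 (-1.21 to -0.41) and mir-549a at -0.75 (-1.003 to -0.49), followed by mir-1225, mir-654, mir-378f, mir-4661, mir-6133, mir-5695, mir-4709 and mir-3196, at -0.57 to -0.45. mir-21, the most abundant hairpin in the cells, held 20.01% of miRNA counts with vehicle and 22.8% with 1,25D. mir-146a was scarce in the culture, with 474 counts with vehicle and 671 with 1,25D, a log2 ratio of 0.11 (-0.058 to 0.29). Scaling by all 6 classes moved the median of the 571 ratios to -0.11 from -0.0062.

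The let-7 family was lower in the 1,25D library in 11 of 12 hairpins, with a median log2 ratio of -0.21, below all 10000 matched random lists. let-7a-1 was at -0.31, let-7b at -0.22 and let-7c at -0.29, while let-7i was at 0.11. The miR-99/100 and miR-125 family, whose genes lie beside let-7 genes, was lower in 6 of 6 hairpins at a median of -0.16, percentile 2.96 of matched lists. The 14q32 cluster was higher in 23 of 33 hairpins, with a median of 0.087 at percentile 96.7, and with scaling by all 6 classes, which moves all hairpins alike, its median was -0.018 at the same 0.093 above the median of all hairpins. The vitamin D-linked miRNAs had a median of -0.043 at percentile 34.9, and the prostate cancer-linked miRNAs -0.052 at percentile 28.5. Medians of the other lists stood at percentile 9.68 for miR-17-92 and its paralogs, 16.3 for stromal and smooth-muscle markers, 24.2 for miR-200 with miR-205, 25.4 for other-organ markers and 28.2 for blood cell markers. The endothelial mir-126 stood at percentile 37.8, the miR-34 family at 43.4, the miR-15/16 family at 52.0 and the miR-183 cluster at 82.8. Copies of 1 mature miRNA share reads, so members of these lists are not independent.

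**Figure D4:**
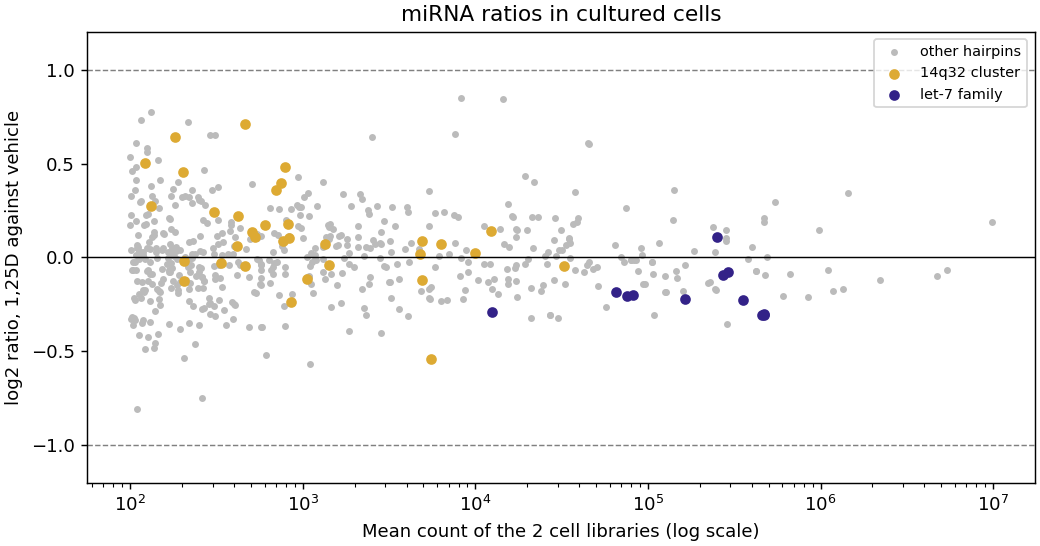
log2 ratio of 1,25D against vehicle in cultured cells (y axis) against the mean count of the 2 cell libraries (x axis, log scale) for 571 miRNA hairpins, 1 library per treatment. Dashed lines mark a 2-fold difference, which 0 hairpins reach, and 11 of 12 let-7 hairpins lie below 0.

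Larger ratios were found in the other classes of the cell libraries. Between the 2 libraries, 4 rRNA features were at least 2-fold higher with 1,25D and 1 lower of 82, 10 tRNA features were higher and 0 lower of 343, and 4 piRNA features were higher and 7 lower of 320. Only 9.9% of tRNA values and 29.1% of rRNA values are whole numbers, so reads may be split between features. Counts of features in these classes need not be counts of separate RNAs. For snoRNA (366 features) and snRNA (109 features) the counts were 0 in both directions. With TMM factors within the class the counts were 6 higher and 1 lower for rRNA, 7 and 5 for piRNA and 2 and 0 for snRNA, and with scaling by all 6 classes 15 and 1, 9 and 5, and 8 and 0. The piRNA features farthest apart in each direction were hsa_piR_004307, at 19339 counts with vehicle and 95359 with 1,25D (log2 ratio 1.44, 1.42 to 1.47), and hsa_piR_003599, at 383 and 2 counts (-8.12, -11.49 to -6.58). hsa_piR_004309 and hsa_piR_017723 were at 1.27 and 1.12, and hsa_piR_019410 and hsa_piR_012647 at -1.88 and -1.84. Among numbered features, 309_rRNA was at 1.69, 429_tRNA at 1.17 and 91_rRNA, with 827 and 31 counts, at -5.72. miRNA took 75.7% of the counts with vehicle and 70.4% with 1,25D, rRNA 5.79% and 8.25%, tRNA 8.41% and 9.78%, and piRNA 2.36% and 3.04%. Exact 95% binomial intervals of these shares were narrow, as for miRNA with 75.73% to 75.75% and 70.41% to 70.43%.

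Vehicle cells were then set against control tissue to see how the culture differs from the epithelium it models. Of 570 hairpins, 143 were at least 4-fold above the mean of the 4 control tissues and above their range, and 113 were at least 4-fold below and under it. Chance alone puts 40.0% of single values outside the range of 4 others, and here 277 of the 570 were above it and 180 below. With CPM of all 6 classes, which moved the median log2 ratio of the 570 hairpins to 1.26 from 0.46, 201 were 4-fold above and 90 were 4-fold below. Cells were sequenced to greater depth, so hairpins scarce in tissue enter on their cell counts. mir-31 stood at 50800 CPM in vehicle cells and at 347.8 CPM ± 204.6 in control tissue (SD, n = 4), 146-fold higher. mir-1304 was 62.2-fold higher, mir-7974 92.9-fold, mir-656 51.9-fold, mir-3662 49.8-fold, mir-2115 48.5-fold, mir-1910 31.7-fold and mir-3176 31.1-fold. mir-1293 and mir-3935 had 3 counts each over the 4 control tissues, with log2 ratios of 9.25 (counting interval 8.57 to 12.40) and 5.44 (4.59 to 8.43). mir-21 stood at 200100 CPM against 28630 CPM ± 16020.

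All 8 stromal and smooth-muscle hairpins in this comparison were lower in cells, at a median log2 ratio of -10.72, below all 10000 matched lists. mir-143 stood at 17.3 CPM in cells and 132900 CPM ± 51660 in control tissue (n = 4), and mir-145 at 14 counts in cells and 9084 CPM ± 8002 in tissue. The 2 copies of mir-133a had 10 and 6 counts in cells, and the 2 copies of mir-199a had 73 and 68. Of the 10 farthest below tissue, the others were mir-363 (-12.86), mir-135a-2 (-9.80), mir-375 (-9.79), a miRNA of luminal and neuroendocrine prostate cells, and mir-20b (-9.67). All 8 blood cell hairpins were lower as well, at a median of -6.21 (percentile 0.02). The epithelial miR-200 family with miR-205 had a median of -0.053 (percentile 74.8), with mir-205 at 1.21 and mir-200c at -0.053.

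**Figure D5:**
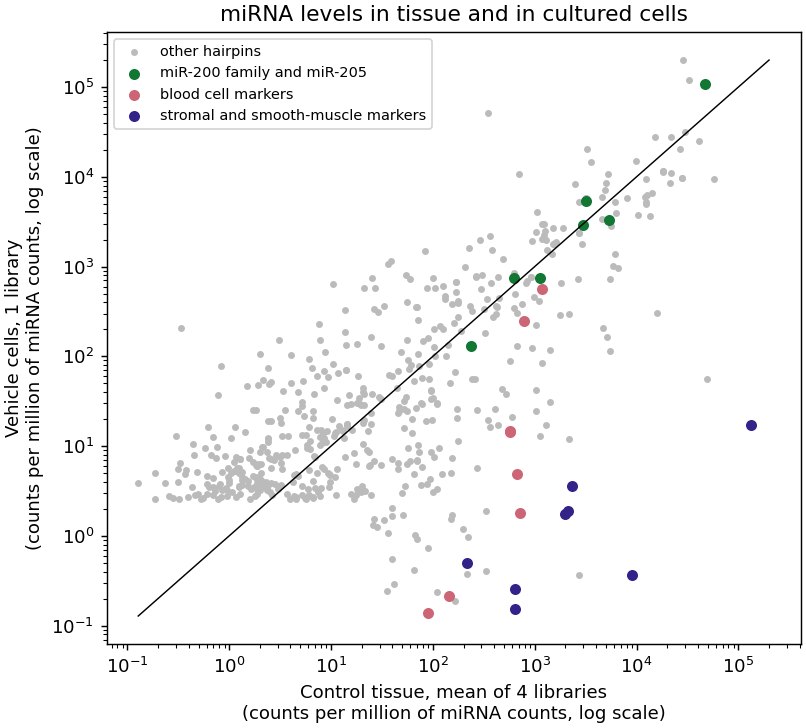
Level of 570 miRNA hairpins in vehicle cells (y axis, 1 library) against the mean of 4 control tissues (x axis), both in CPM of miRNA counts on log scales, with a line at equal levels. The 8 stromal and smooth-muscle hairpins lie far under it, at a median log2 ratio of -10.72, and the miR-200 family with miR-205 lies near it at -0.053.

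The miR-183 cluster was higher in cells in 3 of 3 hairpins, with mir-182 at 2.62 (median at percentile 98.2). The vitamin D-linked miRNAs were higher in 10 of 15 hairpins at a median of 0.95 (percentile 99.9), with mir-21 at 2.81, and the prostate cancer-linked miRNAs in 8 of 11 at a median of 0.92 (percentile 99.6). These lists share members, so their percentiles are not separate results. The whole miR-183 cluster is in the prostate cancer list, and mir-21, mir-182 and mir-106b are in both that list and the vitamin D list. The let-7 family had 10 of 12 hairpins lower, at a median of -0.67 (percentile 53.8), with let-7c at -5.69. The miR-99/100 and miR-125 family was at -2.32 (percentile 4.87), with mir-99a at -5.58. Medians of the miR-34 family (2.51), the miR-15/16 family (0.86), miR-17-92 with its paralogs (0.21) and the 14q32 cluster (0.41) stood at percentiles 90.8, 91.0, 87.6 and 50.7. The miR-17-92 list was divided, with 8 hairpins higher in cells and 6 lower. In it mir-18a was at 4.57 and mir-19a at 3.61, against mir-363 at -12.86, mir-20b at -9.67 and mir-106a at -5.58. In the miR-34 family 2 hairpins were higher, and mir-34a was lower at -0.84. The endothelial mir-126 was at -4.51 (percentile 18.4), and the mir-9 copies had too few counts for this comparison.

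The last comparison asked whether the cell and tissue fold changes go together. Across 408 hairpins, which are not independent replicates, Spearman's rho of the tissue and cell fold changes was -0.097 (two-sided exact permutation p = 0.457), and 196 hairpins had the same sign in both. mir-409 was lower in all 4 high vitamin D tissues than in all 4 control tissues and was at 0.071 (0.020 to 0.12) in the cells, 0.077 above the median of all hairpins under each scaling.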

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

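Each group of 4 tissue libraries was searched for a library far from the other 3, as the gap to its nearest neighbour over the range of the group. Of 138 groups of values, 10 exceeded Dixon's 95% critical value for 4 samples, which chance exceeds in about 1 in 20 groups, or 6.9 of these. Of the tests in this part, those of library composition, of leukocytes as the whole cause and of class totals against the piRNA were chosen after the result was seen.

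The most abundant snoRNA feature held 31.2% of snoRNA counts in control replicate 1 and 14.2% to 16.6% in the other 3 controls (gap ratio 0.856), and the most abundant snRNA feature 20.1% there against 25.8% to 26.9% (0.838). A scarce snoRNA feature, the one called lower with no filter on low counts, stood at 117.2 CPM in the same library and at 14.1 to 27.9 in the others (0.866). mir-148a held 6.66% of miRNA counts in control replicate 4 and 3.22% to 3.37% in the others (0.957), and the mean log2 level of prostate cancer-linked miRNAs was 11.29 there against 10.30 to 10.47 (0.831).

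In high vitamin D tissue, mir-143 held 8.82% of miRNA counts in replicate 2 against 10.5% to 10.8% in the others (gap ratio 0.849). mir-409 stood at 50.4 CPM in replicate 4 against 72.9 to 75.3 (0.905), and the mean log2 level of the mir-9 copies was 4.21 in that replicate against 3.29 to 3.42 (0.857). In replicate 3 the mean log2 level of the miR-15/16 family was 9.03 against 7.93 to 8.06 (0.884), and that of the vitamin D-linked miRNAs 10.64 against 10.14 to 10.19 (0.901).

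mir-409 had values of opposite sign in tissue and in cells: its mean log2 level differed by -0.96 in tissue, with all 4 high vitamin D libraries below the controls, and its log2 ratio in cells was 0.0707. The cell value lay 0.077 above the median of all hairpins under each scaling, and its log2 ratio was -0.0345 with scaling by all 6 classes, which moves all hairpins alike. The difference was not tested, because the cells have 1 library per treatment. Of the named and listed hairpins, 5 had tissue groups that did not overlap and enough cell counts to compare.

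The low level of mir-146a in high vitamin D tissue was weighed against 4 technical explanations. A single library is argued against as the whole cause, since the log2 fold change stayed at -2.45 or lower with any library left out. It ran to -3.94 and was highest without control replicate 4. Its size rests mostly on control replicates 1 and 4, at 2035 and 5626 CPM, against 614 and 395 CPM in replicates 2 and 3. The lane of the 2 differently worded controls is argued against too, since the log2 fold change was -4.01 ± 0.78 (SE) without them. That value rests on the 2 controls left, at 395 and 5626 CPM (edgeR adjusted p = 0.495). mir-142, mir-150, mir-155 and mir-342, taken as leukocyte markers, differed by a mean of -0.721 ± 0.219 on the log2 scale (exact permutation p = 0.0286, the smallest possible), less than the 1 set in advance, and mir-146a differed by -2.16 ± 0.80 beyond that; mir-155 and mir-342 also had 21886 and 9810 counts in vehicle cells, so they are not leukocyte markers alone. Fewer leukocytes may thus account for part of the difference. Whether they account for all of it these values cannot decide, since markers that epithelial cells also express can understate a fall in leukocytes. By class totals, mir-146a itself was scarce in vehicle cells, at 12.1 CPM against a mean of 2188 CPM in control tissue. Chance stays open: 15 of 546 hairpins (2.75%) had groups that did not overlap where chance gives 2.86%, mir-146a was picked for its p, and a response to vitamin D remains an untested hypothesis.

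The low level of stromal and smooth-muscle miRNAs in cultured cells, led in control tissue by mir-143 at 132900 CPM and mir-145 at 9084 CPM, was weighed against the make-up of the libraries and against stromal RNA in the tissue. Composition moves all hairpins of a library alike, as TMM scaling does, and is therefore argued against as the whole cause of a gap between hairpins. The list lay -11.2 on the log2 scale from the median of all hairpins, which was at 0.465, with a quartile spread of 2.19. Scaling cannot change this gap, so the value restates the low level in cells and is not a separate test. RNA from stromal cells in the microdissected tissue, which the capture was meant to leave out, stays open: mir-143, mir-133a and mir-199a had a mean pairwise rho of -0.19 over the 8 tissues, percentile 16.7 of random triples. That is below their median of 0.071, the bound set in advance against this explanation, but by less than their SD of 0.27. The requirement to pass the SD was applied after the value was seen, and stromal RNA therefore cannot be told apart from a loss of expression in culture, which was not tested.

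hsa_piR_016735 took 47.9% to 78.6% of piRNA counts in the 8 tissue libraries. The same reads counted again in a single feature of another class are argued against: the one that came closest, mir-10b, differed 7.04-fold in the library where they were farthest apart. The bound set in advance was on single features, which is too narrow, since only 9.9% of tRNA values are whole numbers and reads split over copies would match no single feature. The totals of rRNA, snoRNA, snRNA and tRNA were 0.571, 0.453, 0.0626 and 0.485 of its count in the library where each was lowest, so not all of its reads were counted again in any of these 4 classes. Counting of part of its reads there, or of its reads over several miRNA features, stays open, and no biological explanation was tested.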

How the results depend on the processing

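Alternatives were set before the data were examined, except summing copies of 1 miRNA and, for lists, the library size over all classes, which were chosen after seeing the data. The replicate numbers did not pair the libraries (correlations of same-numbered miRNA deviations ran from -0.063 to 0.31, and not every library correlated best with its own number), so the paired fit with a replicate block is only a check; it called 0 features in each class and 3 lists, as without the block. Leaving out each library in turn, edgeR called 0 features in each class, and 0 class shares passed. The exact test of class shares could hardly pass here, since a single class at its smallest possible p does not pass after adjustment. DESeq2 called 1 miRNA, and no filter on low counts called 1 snoRNA and 17 piRNA features, where the main test called 0; the cause was not tested. limma-voom and RLE factors called 0 in each class. Library sizes over all 6 classes called 0 too but shifted the median log2 fold change by -0.22 for miRNA, 0.27 for snoRNA, 0.19 for snRNA and -0.75 for tRNA.

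The count of lists past the threshold, 3, became 0 with an estimated correlation and 1 to 7 with 1 library left out. The 14q32 call ended without control replicate 2 or 3 (adjusted p 0.438 and 0.827) or high vitamin D replicate 1, 2 or 4 (0.128, 0.143 and 0.362), and the mir-9 call without control replicate 3 (0.172), without the 2 differently worded controls (0.080) and without the filter (0.177). The let-7 call ended without high vitamin D replicate 1 or 2 (0.201 and 0.143), and its direction turned without control replicate 1 (median -0.047, adjusted p 0.481) and without the 2 differently worded controls (-0.11). let-7 was not called with copies summed (0.133) or without the filter (0.141). Blood cell markers were called with copies summed (0.0381), without the filter (0.0270), without the 2 controls (0.0051), without control replicate 1 (0.0125) and without high vitamin D replicate 4 (0.0299). Vitamin D-linked miRNAs were called without the 2 controls (0.0307), control replicate 1 (0.0139) or high vitamin D replicate 3 (0.0446), and miR-15/16 without the 2 controls (0.0307) or control replicate 1 (0.0102). Without control replicate 4, miR-17-92, miR-200 with miR-205, miR-99/100 and prostate cancer-linked miRNAs were called (0.0467 each). Without the 2 controls the camera direction also turned, at medians of 0.081 for miR-17-92, -0.78 for miR-183, -0.10 for miR-200 with miR-205, 0.029 for miR-99/100 and -0.12 for prostate cancer-linked miRNAs, none called in the main test. It turned too for miR-183 with RLE factors (-0.28) and without the filter (-0.33), for stromal markers with copies summed (-0.21) and without the filter (-0.17), for prostate cancer-linked miRNAs without the filter (0.043), and for miR-15/16 with the library size of all classes (-0.32). With 1 library left out, medians ran from -0.047 to 0.40 for let-7, -0.42 to 0.12 for miR-15/16, -0.18 to 0.33 for miR-17-92, -0.51 to 0.36 for miR-183, -0.28 to -0.022 for miR-99/100, -0.29 to 0.31 for prostate cancer-linked miRNAs and -0.20 to 0.19 for stromal markers. They also ran from -0.51 to -0.14 for 14q32, 0.50 to 1.61 for mir-9 and -0.013 to 0.38 for miR-200 with miR-205. For vitamin D-linked miRNAs they ran from -0.35 to -0.11, and for blood cell markers from -0.51 to -0.18.

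Without the 2 differently worded controls the tRNA share difference turned to 4.71 percentage points from -3.24, and mir-138-2 to 0.21 from -2.14. With 1 library left out the tRNA difference ran from -6.18 to 3.20 and the miRNA difference from -6.69 to 0.33. The 10 most abundant miRNAs took 21.2% of the counts of 6 classes together, by the wider denominator, against 47.5% of miRNA counts. At a count minimum of 20 in cells, 14 of 1046 miRNAs differed 2-fold, where none did at 100; higher and lower features were then 16 and 40 for piRNA (4 and 7 at 100), 7 and 6 for rRNA (4 and 1), 5 and 0 for snRNA (0 and 0), 2 and 5 for snoRNA (0 and 0) and 10 and 2 for tRNA (10 and 0), and the added ones rest on few counts. Spearman's rho of tissue and cell fold changes ran from -0.148 to -0.00934 with 1 library left out. For these turned or changed values the cause was not tested. The direction is camera's and the value the list median, which can differ in sign. Of the values that answer a comparison, 127 kept their direction and side of the threshold or stayed near the main value, and 11 moved. Of those for single features, shares and lists, 616 stayed, 34 reversed, 18 came to pass the threshold, 15 no longer passed it and 9 moved, the last all shares of 6 classes in place of 1. The 127 and the 616 include mean shares of the most abundant miRNAs with 1 control library left out. Their bound was the SD of the 4 controls, which leaving out 1 of 4 values cannot exceed. These shares were thus bound to stay and are no sign of stability. The subclass comparison of numbered RNAs was not run, since the features carry no subclass.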

Other observations

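Of the features at an unadjusted p under 0.05 in tissue with enough cell counts, 6 of 7 rRNA, 6 of 7 snRNA, 13 of 19 tRNA, 7 of 12 snoRNA, 4 of 10 piRNA and 6 of 12 miRNA features had the same sign in cells, against 50 of 73, 59 of 88, 175 of 319, 186 of 344, 148 of 257 and 198 of 419 among all tested, in the same order of classes. Features of a class are not independent, and this tally and the 2 agreeing features given here were chosen after values were seen. An rRNA feature at an unadjusted p of 0.0232 in tissue, not the smallest of its class, was at a log2 fold change of 0.93 ± 0.34 (SE) with high vitamin D, and was at 1.18 (counting interval 1.06 to 1.31) with 1,25D in cells. An snRNA feature was at 0.64 ± 0.21 in tissue and at 0.91 (0.83 to 0.99) in cells. Neither passed in tissue (edgeR adjusted p of 0.659 and 0.628).

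Of the tested hairpins, 3 overlap nuclear copies of mitochondrial genes by GENCODE release 29 (assembly GRCh38). mir-4485, inside MTRNR2L8, was at a log2 fold change of 1.98 ± 0.54 (SE) in high vitamin D tissue, mir-4461, inside MTND4LP30, at 1.55 ± 0.56, and mir-6723, inside MTCO1P12, at 1.34 ± 0.54. In cells with 1,25D they were at 0.41 (0.07 to 0.77), 0.20 (0.12 to 0.27) and 0.35 (0.30 to 0.41). None passed in tissue (edgeR adjusted p of 0.879, 0.917 and 0.917). Without high vitamin D replicate 4, mir-4485 was at 1.30 and mir-4461 at 0.98 in tissue. The group was formed after mir-4485 and mir-4461 had been seen among the hairpins of smallest p, so their shared direction in tissue is not independent support.

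The counts of tissue features at an unadjusted p under 0.05 were set against the 35 splits of the 8 libraries into 4 and 4. For miRNA, 27 splits gave at least the real 15, with a highest other of 89. This count of splits includes the real split itself, as do those that follow. For snoRNA it was 18 splits (real 16, highest other 90), for snRNA 14 (10, 28), for tRNA 16 (22, 108), for piRNA 12 (24, 70) and for rRNA 19 (7, 22). At least 3 lists past the threshold were given by 20 splits, the real one included, the highest other giving 8. Chance is not excluded for any of these. Some splits gave several times the real count, which may reflect a structure of the libraries other than the supplement group or features that vary together, and neither was tested.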
